A study of Homo sapiens with 10 samples.

How the data were processed

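Antrum biopsies of 5 control patients and 5 patients with active eosinophilic gastritis (EG) were each measured on 1 Affymetrix U133 Plus 2.0 array. Per the labels' protocols, the tissue was kept in RNAlater, total RNA was extracted with the miRNeasy kit and checked on a Bioanalyzer, and it was amplified in 1 round of in vitro transcription primed with both oligo-dT and random T7 primers before biotin labelling. The mixed priming bears on 3' to 5' signal, since random primers also copy the 5' part of a transcript. Background correction, normalization and summarization were done with RMA, per the submitters' processing notes, and its version is not given in the sources used here.

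The deposited values are linear ratios: each probe set of each array is given relative to the median of the 5 control arrays. This scaling is not described in the labels and was found from the values, since the control median was 1 within a tolerance of 0.0006 for each of the 54675 probe sets, and the lowest ratio was 0.01. The scaling removes the brightness of a probe set, so dim probe sets could not be filtered and no level can be set against that of another gene. It also pulls the control arrays toward 0, so that the spread of an array around the control median is smaller in controls by construction and was not compared. The array medians were 1.0 in each control array and ranged from 0.985 to 1.047 in EG. Array files from the scanner were not used here.

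Ratios were taken to log2, with no pseudocount. Groups came from the source labels of the samples, and replicate numbers were given in accession order and pair nothing. Probe sets were named through the platform annotation, and symbols were updated through their gene identifiers to the RefSeq annotation of GRCh38.p14. Of the probe sets, 41091 had 1 gene, 1801 had several, 11721 had none listed and 62 were control probe sets. The identifier matched for 41037 of those with 1 gene, and the platform's symbol was kept for 54. Probe sets with several genes or none, control probe sets, and X-inactivation and Y-linked genes were left out of the gene tests, which left 41028 probe sets of 19738 genes. Of 485 genes in the lists, 445 had a probe set of their own; the other 40 were not analysed here, among them CCR3 and RNASE3. The plan was to keep for each gene the probe set with the highest mean, or, for a table centred per probe set, the one with the largest variance over the 10 arrays, and the latter applied. This choice favours probe sets with large differences, so the mean of a gene's probe sets was among the alternatives. In 10509 genes with several probe sets, 5875 had differences of 1 sign in each probe set. Of the genes named with several probe sets, SOCS1, MPV17L, TRAF5, FNDC3B and MUC4 had a probe set of the opposite sign.

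Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the factor, and p-values were adjusted by Benjamini-Hochberg over the genes tested at a threshold of 0.05. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists, with an estimated correlation and fry beside it. Members of a list were also adjusted over the list alone. Single measures were compared by exact two-sided permutation tests over every assignment of the 10 arrays to groups of 5. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the 10 genes with the largest and the 10 with the smallest change among those past the threshold with separate groups, of which there were 0, up to 4 members of each list with the smallest adjusted p, any member of the eosinophil, type 2 cytokine, CCR3 ligand and IL-13 lists, and 18 genes in any case (CLC, CCL26, CCL11, CCL24, IL4, IL5, IL13, IL33, TSLP, CDH26, IL13RA2, TPSAB1, CPA3, GAST, SST, MUC5AC, ATP4A and MKI67). HPDL, MORF4L2-AS1, MPV17L, TRAF5, FNDC3B, KRT13, MUC4, GOLIM4, KIT, CMA1 and FCER1A were named after their values were seen.

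The gene test was tested on simulated data, with the measured residual SD of each of the 19738 genes and 200 changed genes in each of 5 draws. It recovered 62.8% of 2-fold, 94.0% of 4-fold and 98.0% of 8-fold changes, and 5.3% of calls were unchanged genes. The simulated values were independent between genes and had the same spread in both groups. In some measured genes the spread was not alike, such as CCL26, with an SD of 3.04 in EG and 0.13 in controls. The shares recovered do not carry over to such genes. With a shifted list in each draw, camera called 5 of 5, and it called 0 of 135 unshifted lists. The lists called in the measured data had estimated correlations of 0.099 to 0.805 between members. The counts from independent simulated genes therefore do not carry over to them.

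Alternatives were repeated quantile normalization, median-centring of the arrays, the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, each probe set on its own, array weights, unequal spread per gene, exact permutation per gene, other thresholds, a test against a 1.5-fold change, the 3' to 5' difference as a covariate, other list tests, lists without shared genes, and leaving out each array in turn. After the data were seen, 6 more were added: a robust prior, a filter on low variance, leaving out the 3 arrays of highest 3' to 5' difference or of highest squamous list mean, the subepithelial list mean as a covariate, and an exact permutation test of list means. No array duplicated another, since the smallest root mean square difference between any pair was 0.312 on the log2 scale. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 prepared the table and drew the plots.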

Results

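Biopsies of the gastric antrum, the lower part of the stomach, were taken from 5 control patients and 5 patients with active eosinophilic gastritis (EG), a disease in which eosinophils gather in the stomach wall. RNA of each biopsy was measured on a whole-genome 3' expression array, with 1 array per patient, and the comparison asks how gene expression in the antrum differs between the groups. The table gave 54675 probe sets per array as ratios to the median of the 5 control arrays, so a log2 value of 0 marks the control median and the brightness of a probe set is not kept. Values below are log2 ratios, as mean ± SD with n = 5 per group, and differences are EG minus control ± SE from limma. A total of 19738 genes were tested. The number of arrays limits the precision of every value.

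The arrays differed in signs of RNA quality. The difference between the 3' and the 5' control probe sets of ACTB and GAPDH, which grows when RNA is broken, was 0.41 ± 0.83 in EG and 0.14 ± 0.29 in controls (log2, n = 5 each, exact two-sided permutation p = 0.468). It was highest in EG 3 and EG 5, at 1.31 each, and next in control 5, at 0.62. The other 7 arrays lay between -0.30 and 0.21. Medians and interquartile ranges of the arrays could not be compared between the groups, because the ratios are centred on the controls.

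No gene passed the test over all genes. With limma, 0 genes were higher and 0 lower in EG at an adjusted p under 0.05, and the smallest adjusted p was 0.172, shared by 105 genes. At an unadjusted p under 0.05 there were 3171 genes, 1702 higher and 1469 lower, where 987 would be expected with no difference. Testing each gene with unequal spread gave 0 genes after adjustment and 2546 at an unadjusted p under 0.05. An exact permutation test per gene gave 0 and 2885, but to pass any gene it needs at least 3134 genes at its smallest possible p, or more at a larger p. In 608 genes the 5 EG values lay on one side of the 5 control values, which is 3.08% of genes, where chance gives 0.794%. The expected numbers do not show how far such counts vary between splits of the arrays. Of 100 splits, the real one included, 5 gave at least 3171 genes at an unadjusted p under 0.05. Separated genes were not counted in the other splits. Leaving out EG 2 alone gave 111 higher and 130 lower genes at an adjusted p under 0.05.

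Of the 28 gene lists fixed before the data were examined, limma's camera test with a preset correlation called 9 higher and 1 lower in EG. None of the 10 calls held with an estimated correlation (adjusted p = 0.73 for each of the 10), nor with fry. The exact permutation test of list means, which to call any list needs at least 5 at its smallest possible p, or more at a larger p, called 0, and 1 list reached that p. Among 100 splits of the 10 arrays into 5 and 5, the real one included, 49 gave at least 10 called lists. The single genes described below are given with p-values adjusted over each list alone, as planned. This adjustment does not correct across the 28 lists, and some genes belong to more than 1 list. It is therefore laxer than the test over all genes, which none of these single genes passed.

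Of 21 measured epithelial genes that IL-13, a type 2 cytokine, is known to induce, 8 rose in EG and 1 fell when adjusted over the list alone, CDH26, IL13RA2 and CCL26 with the smallest p among them. CCL26 encodes eotaxin-3, a chemokine that draws eosinophils. It rose 24.7-fold, from 0.04 ± 0.13 in controls to 4.67 ± 3.04 in EG (n = 5 each, difference 4.62 ± 1.21, adjusted p = 0.0229 over the list alone and 0.184 over all genes in limma), and the 5 EG arrays spread from 0.47 in EG 2 to 8.69 in EG 1. The difference was 3.62 without EG 1, 5.67 without EG 2 and 2.93 without the 3 arrays of highest squamous list mean. The cadherin gene CDH26 rose 12.3-fold (3.61 ± 0.63, adjusted p = 0.00359 over the list alone), with each of its 4 probe sets higher and a difference of 1.71 for their mean. IL13RA2, a decoy receptor for IL-13, rose 3.83-fold (1.94 ± 0.47, adjusted p = 0.0219 over the list alone). Of the 21 measured members, 9 passed when adjusted over the list alone and 0 over all genes. Tested with unequal spread per gene, 0 passed over the list alone. SOCS1 and CISH, which restrain cytokine signalling, rose by 0.56 ± 0.16 and 0.60 ± 0.22, ALOX15, a lipoxygenase, by 0.40 ± 0.13, FCGBP by 1.34 ± 0.44 and the cystatin gene CST2 by 0.28 ± 0.10. The difference of SOCS1 was 0.18 for the mean of its probe sets, and without the 3 arrays of highest squamous mean that of IL13RA2 was 1.21, of SOCS1 0.37 and of CISH 0.35. DPP4, a peptidase that belongs to the list, moved the other way and fell by 1.54 on the log2 scale (SE 0.49), and 12 members did not pass. Whether passing or not, 15 members were higher and 6 lower, with CLCA1 at -1.10 ± 0.57 among the lower ones. The list was drawn from what is known of eosinophilic disease, possibly including these samples, so its count is not fully independent evidence. The list mean was 0.61 ± 0.40 in EG and 0.02 ± 0.09 in controls (camera adjusted p = 0.00932; adjusted p = 0.73 with an estimated correlation), and its exact permutation p was 0.00794, the smallest possible (0.20 after adjustment over the 28 lists). The 9 became 1 without control 4, 2 without control 1, 4 without control 2, EG 1 or EG 5, 5 without EG 3 or EG 4, and 0 without the 3 arrays of highest 3' to 5' difference, where the list mean difference was 0.66. The list call was lost without the genes that another list holds, CCL26 and CDH26 among them (mean difference 0.21, adjusted p = 0.115).

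**Figure D1:**
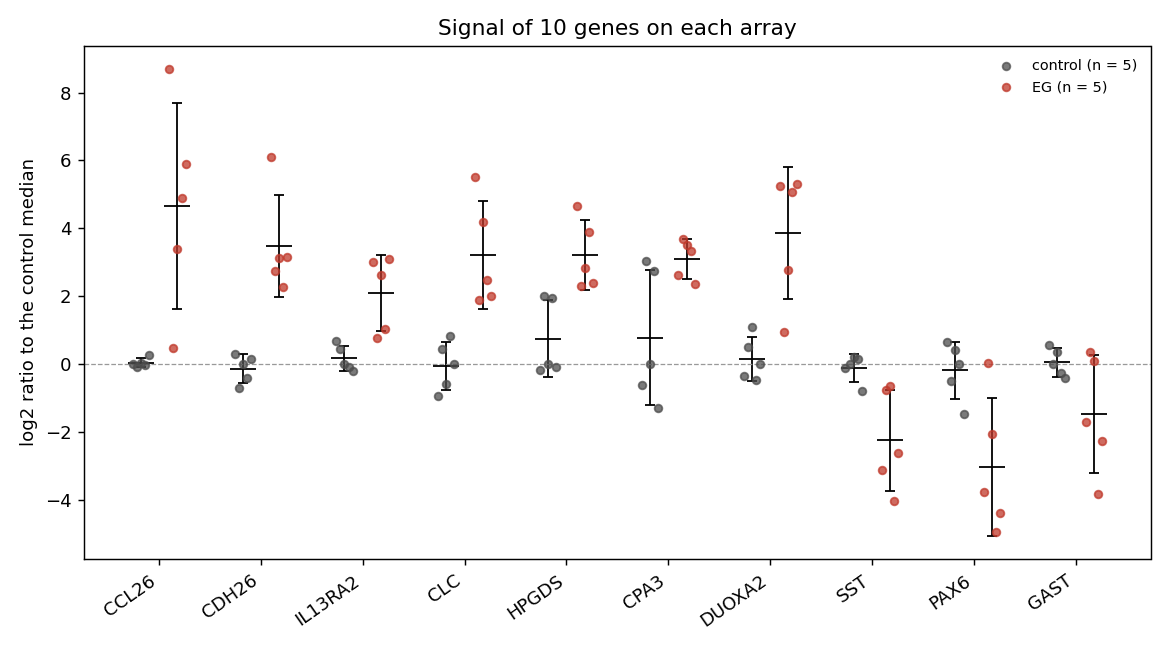
Signal of 10 genes on each array, on the y axis as log2 ratio to the control median, with control arrays in grey and EG arrays in red (points, n = 5 per group) and the mean ± SD as black bars. CCL26 spans 0.47 to 8.69 in EG, CDH26 is 2.27 or more on each EG array, and SST is below 0 on each EG array. For SST, control 5 at -0.80 lies below EG 2 at -0.78 and EG 3 at -0.65.

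Ligands of CCR3, the eotaxin receptor, gave 1 member past the threshold when adjusted over the list alone, CCL26, out of 7 measured. CCL24 had a difference of 0.35 ± 0.14 (adjusted p = 0.107 over the list alone). CCL11, eotaxin-1, stood at 2.69 ± 1.46 in EG against 1.53 ± 2.16 in controls. Its difference of 1.16 ± 1.04 did not pass (limma adjusted p = 0.353 over the list alone). The difference ran from 0.65 without EG 3 to 1.79 without control 2. It was -0.03 with the subepithelial list mean as a covariate, and CCL11 stood at 4.02 and 3.76 in control 2 and control 4, the controls with the highest subepithelial means. The list was not called (adjusted p = 0.537). Type 2 cytokines and their receptors were not called either (mean difference 0.07, adjusted p = 0.242), with 0 of 16 measured members past the threshold adjusted over the list alone. Leaving out 1 array moved the mean difference between 0.04 (control 5) and 0.11 (EG 5). IL13 differed by 0.23 ± 0.12 (0.15 without EG 1), IL5 by 0.13 ± 0.09 and IL4 by 0.08 ± 0.09 (0.03 without EG 5 and 0.13 without control 5). The epithelial alarmins IL33 and TSLP had differences of -1.16 ± 0.75 and -0.20 ± 0.37.

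Among eosinophil markers, CLC and IL5RA rose. CLC, which encodes the Charcot-Leyden crystal protein, rose 9.64-fold, from -0.05 ± 0.71 to 3.21 ± 1.58 (difference 3.27 ± 0.69, adjusted p = 0.0101 over the list alone and 0.172 over all genes). IL5RA, the receptor chain for IL-5, rose 1.77-fold (0.83 ± 0.23, adjusted p = 0.0326 over the list alone) by the probe set kept of its 4, but its difference was 0.37 for the mean of the 4 and 0.02 without probe sets that can match several transcripts. The other 11 of 13 measured members did not pass, among them ADGRE1 at 0.94 ± 0.37, SIGLEC8 at 0.36 ± 0.16 and RNASE2 at 0.38 ± 0.20, which were 0.57, 0.21 and 0.19 without EG 1. The granule protein genes EPX, PRG2 and PRG3 differed by 0.07 ± 0.14, 0.04 ± 0.07 and 0.03 ± 0.11. Leaving out 1 array moved EPX between 0.01 (control 4) and 0.17 (control 5), PRG2 between 0.02 (EG 3) and 0.07 (control 5) and PRG3 between -0.02 (control 2) and 0.11 (control 5). The list mean was 0.53 higher in EG (camera adjusted p = 0.0282; adjusted p = 0.73 with an estimated correlation; exact permutation p = 0.0159 before adjustment). Its call was lost without control 1 (adjusted p = 0.0533) and without control 2 (0.0778), as well as without probe sets that can match several transcripts (0.0687). The 2 members became 1 without control 1, 2, 3 or 5 or without EG 3 or 5, 3 without EG 1, and 0 with unequal spread per gene.

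Of 18 measured mast cell markers 7 rose in EG when adjusted over the list alone, 11 did not pass, and 0 passed over all genes. Each of the 18 lay above the control mean. Among the 11, KIT differed by 0.19 ± 0.42, CMA1 by 0.10 ± 0.16 and FCER1A by 0.64 ± 0.62. MS4A2 had no probe set of its own. HPGDS, the hematopoietic prostaglandin D synthase, rose 5.55-fold (2.47 ± 0.61, adjusted p = 0.0408 over the list alone), RGS13 rose 8.41-fold (3.07 ± 0.96), the mast cell carboxypeptidase gene CPA3 rose 5.02-fold (2.33 ± 0.83) and the tryptase gene TPSAB1 rose 2.21-fold (1.14 ± 0.38). IL1RL1, the receptor for IL-33, rose 1.66-fold (0.73 ± 0.23). For the mean of their probe sets the differences of RGS13, TPSAB1 and IL1RL1 were 1.57, 0.61 and 0.42, and that of CPA3 was 1.41 with the subepithelial list mean as a covariate. The list mean was 1.04 ± 0.21 in EG and 0.19 ± 0.62 in controls (camera adjusted p = 2.7e-04; adjusted p = 0.73 with an estimated correlation). Control 2 and control 4 stood at 0.88 and 0.86, within the EG range of 0.69 to 1.20, and both controls also carried high means of fibroblast genes, 2.14 and 1.04. CPA3 stood at 3.04 and 2.73 in these controls, above EG 1 and EG 5 at 2.61 and 2.35. TPSAB1 stood at 1.26 in control 2, above EG 1 and EG 5 at 1.13 and 0.74. HPGDS lay above each control array on each EG array. The 7 became 0 without control 1, 3 or 5 or without EG 1 or 3, 1 without EG 2 or 4, and 4 without EG 5. They became 1 after quantile normalization or median-centring of the arrays, and 0 with unequal spread per gene. Genes of eicosanoid enzymes and receptors were also called (mean difference 0.51, camera adjusted p = 0.0167; adjusted p = 0.73 with an estimated correlation), with HPGDS the 1 of 20 members past the threshold adjusted over the list alone, and the call was lost without control 1 (0.0533), without EG 2 (0.14), without genes that another list holds (0.0941) and with the subepithelial list mean as a covariate (mean difference 0.31, 0.0702).

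Among leukocyte adhesion genes 4 of 14 measured members passed when adjusted over the list alone. CDH26, MADCAM1 (0.67 ± 0.17), the vascular address for gut-homing lymphocytes, and SELP (0.55 ± 0.18), P-selectin, rose, and ICAM2 fell by 0.90 on the log2 scale (SE 0.30). SELP differed by 0.27 without the 3 arrays of highest squamous mean. The list itself was not called (adjusted p = 0.0758), but was without control 2 or 4 or EG 1 or 4 (0.00547 to 0.0366). In the type 17 list the genes of the epithelial hydrogen peroxide enzyme DUOX2 and its maturation factor DUOXA2 rose, 4.99-fold (2.32 ± 0.58) and 13.2-fold (3.72 ± 0.82), with adjusted p of 0.0194 and 0.0151 over the list alone. The other 13 of 15 measured members did not pass, and the list was not called (adjusted p = 0.0791), but was without control 2 or EG 3 or 4 (0.0273 to 0.0438).

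Enteroendocrine genes formed the 1 list called lower, with 17 of 20 measured members below the control mean. The list mean was -1.46 ± 1.22 in EG and -0.06 ± 0.46 in controls (difference -1.40, camera adjusted p = 1.9e-07; adjusted p = 0.73 with an estimated correlation; exact permutation p = 0.0635 before adjustment). The shift lay in EG 1, EG 4 and EG 5, at -1.98, -2.62 and -2.38. EG 2 and EG 3 stood at 0.07 and -0.41, and control 5 at -0.86. EG 1, EG 5 and control 5 also had the highest squamous list means, 1.38, 1.22 and 2.27, against 0.16 in EG 4, and the difference was -1.12 without these 3 arrays. When adjusted over the list alone 0 members passed, with a smallest value of 0.0563. SST, the gene of somatostatin, differed by -2.13 ± 0.61, and PAX6, PCSK1N and INSM1 by -2.86 ± 0.87, -1.38 ± 0.44 and -2.38 ± 0.81. The value of INSM1 depends on the probe set, with -0.22 when probe sets that can match several transcripts are left out and -1.30 for the mean of both. GAST, the gene of gastrin, differed by -1.52 ± 0.71 (adjusted p = 0.083 over the list alone), and by -0.93 without EG 4.

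Other epithelial lists were not called. Gastric surface and antral gland genes had a mean difference of -0.20 (adjusted p = 0.0758, or 0.0167 without control 2 and 0.0273 without EG 4), with SULT1C2 at -1.03 ± 0.30 and the surface mucin gene MUC5AC at -0.94 ± 0.47, each at -0.44 for the mean of its probe sets. Parietal and chief cell genes varied widely within both groups, from -1.81 to 1.66 in EG and from -1.43 to 1.00 in controls (mean difference -0.13, adjusted p = 0.556, or 0.0395 without EG 4), and ATP4A, the proton pump gene, differed by -0.47 ± 1.15. Intestinal epithelial genes differed by -0.28 (adjusted p = 0.171), by -0.44 without control 4 (0.0238) and by -0.04 without control 5 (0.821). CDH17 differed by -0.78 ± 0.31 (-0.52 without control 5 and -0.40 without the 3 arrays of highest 3' to 5' difference), and epithelial junction genes by 0.07 (0.537). Squamous epithelial genes, which the antrum should lack, differed by 0.17 (0.904) but stood at 2.27 in control 5, 1.38 in EG 1 and 1.22 in EG 5. The squamous difference was 0.64 without control 5 (0.076) and -0.04 without EG 1 (0.562).

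Cell cycle genes had 20 of 20 members above the control mean (mean difference 0.72, camera adjusted p = 0.0029; adjusted p = 0.73 with an estimated correlation), and 0 passed when adjusted over the list alone. AURKA differed by 1.27 ± 0.43, RRM2 by 1.45 ± 0.52 and MKI67 by 0.75 ± 0.46. The call was lost without EG 2 (adjusted p = 0.14) and without control 5 (mean difference 0.46, adjusted p = 0.1), whose list mean was -1.22. Without the 3 arrays of highest squamous mean the list differed by 0.07 (adjusted p = 0.863), AURKA by 0.46, RRM2 by 0.61 and MKI67 by 0.16, and AURKA differed by 0.20 without probe sets that can match several transcripts. Lists of subepithelial and myeloid cells were called higher as well, each with 0 members past the threshold adjusted over the list alone and each with an adjusted p = 0.73 with an estimated correlation. These were macrophage and dendritic cell markers (mean difference 0.61, camera adjusted p = 0.0269), fibroblast and matrix genes (0.85, 0.0341), endothelial markers (0.40, 0.047) and neutrophil markers (0.34, 0.0473). CCL18, a macrophage chemokine, differed by 3.13 ± 0.80 (adjusted p = 0.0607 over the list alone), the matrix gene TNC by 1.62 ± 0.73 (0.91 without control 5 and 0.64 for the mean of its probe sets), TIMP1 by 0.94 ± 0.33, VWF by 0.87 ± 0.29 and the neutrophil receptor gene CXCR2 by 0.49 ± 0.16. The joint mean of the fibroblast, endothelial and smooth muscle lists was 0.72 ± 0.45 in EG and 0.07 ± 1.12 in controls (exact permutation p = 0.286), and was -1.41 in control 5. Leaving out single arrays also ended calls: macrophage without control 1 or 5 or EG 2 or 3 (adjusted p 0.0671 to 0.251), fibroblast without control 1, 3 or 5 or EG 2, 3 or 5 (0.0611 to 0.452), endothelial without control 1, 3 or 5 or EG 2 or 3 (0.105 to 0.329), and neutrophil without control 1, 3 or 4 or EG 2 or 5 (0.0637 to 0.187). Control 5 and control 2 moved the differences most, to 0.34 without control 5 and 1.33 without control 2 for fibroblast genes and to 0.20 and 0.62 for endothelial markers. Without the 3 arrays of highest 3' to 5' difference the fibroblast list differed by 0.06 (adjusted p = 0.955), the endothelial list by 0.09 (0.881) and the macrophage and dendritic cell list by 0.25 (0.596). With the subepithelial list mean as a covariate the macrophage and dendritic cell list differed by 0.18 (0.658), the neutrophil list by 0.34 (0.129) and the cell cycle list by 0.55 (0.0727).

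**Figure D2:**
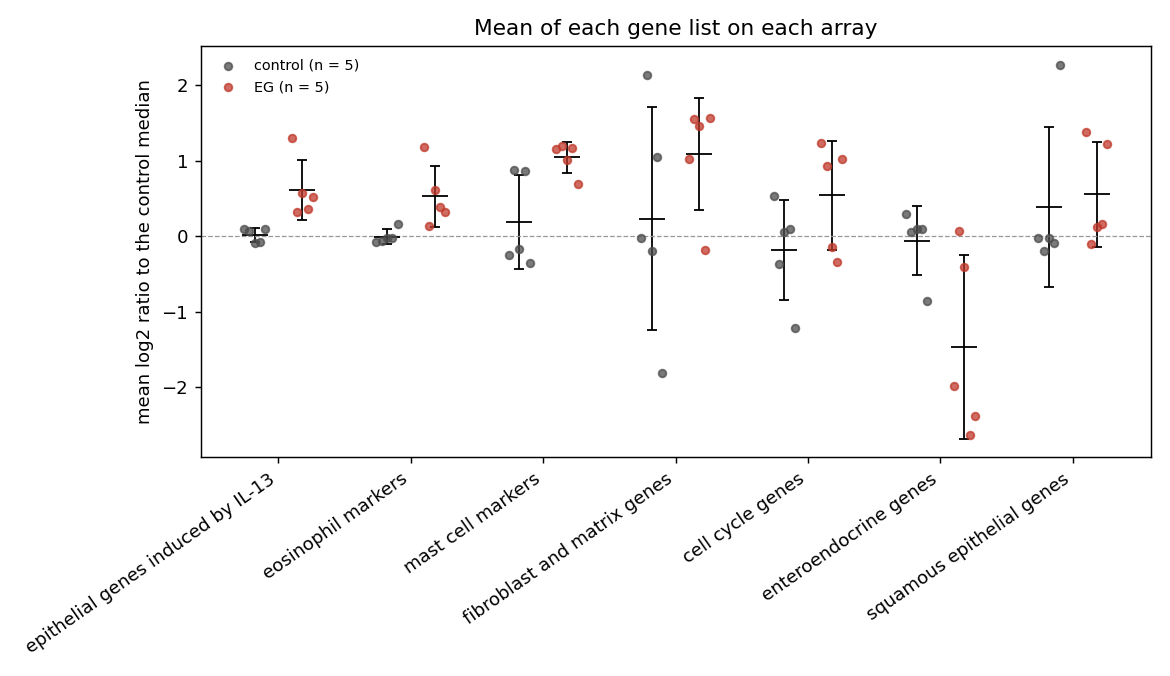
Mean of 7 gene lists on each array, on the y axis as log2 ratio to the control median, with control arrays in grey and EG arrays in red (points, n = 5 per group) and the mean ± SD as black bars. The IL-13 list of each EG array lies above each control array, 3 EG arrays lie near or below -2 for enteroendocrine genes, and control arrays span -1.81 to 2.14 for fibroblast genes.

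The lists left over were not called. Interferon-gamma response genes differed by 0.08 (adjusted p = 0.556), with WARS1 at 0.90 ± 0.24 (adjusted p = 0.0612 over the list alone) and IFNG at 0.25 ± 0.12, and type I interferon response genes by 0.02 (0.566). T cell markers differed by -0.09 (0.486), with CD5 at 0.51 ± 0.17 and TRAT1 at -0.55 ± 0.21, and B cell markers by -0.01 (0.486). Plasma cell markers differed by 0.43 (0.205), smooth muscle markers by 0.67 (0.0758), neural and glial markers by -0.002 (0.533), red blood cell genes by 0.21 (0.205) and immediate early genes by 0.35 (0.0791). Leaving out 1 array brought a call for plasma cell markers (control 2 or 4 or EG 4, 0.00588 to 0.0273), smooth muscle markers (control 2 or 4 or EG 1 or 4, 9.8e-04 to 0.0366) and immediate early genes (control 3 or EG 3, 0.0345 and 0.0146). Plasma cell markers differed by 0.73 without control 2 but 0.22 without control 5, and smooth muscle markers by 1.04 and 0.27. Immediate early genes differed by 0.45 without EG 3 and 0.16 without EG 1. Red blood cell genes differed by 0.27 without EG 2 and 0.13 without EG 1. The mean and the direction of the camera test were of opposite sign for B cell, neural, type I interferon, squamous and junction genes, and for B cell and neural genes the median member, at 0.08 and 0.18, was above 0 while the mean was below it.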

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

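The tests of the explanations in the last paragraph of this part were chosen after the results were seen. Across 188 groups of 5 values, 13 held an array far from the other 4, with a gap to the nearest of them of more than 0.71 of the range, where chance gives about 9.

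Squamous genes set control 5 apart. Its squamous list mean was 2.27, against -0.20 to -0.02 in the other control arrays, and KRT13, a keratin of squamous epithelium, stood at 5.68 against at most 0.05. In the same array the enteroendocrine list was the lowest of the controls, at -0.86 against at least 0.06, and the eosinophil list the highest, at 0.16 against at most -0.02. CCL18 stood at 2.51 in control 2, against at most 0.23 in the other controls, CST2 at -0.28 in control 2, against at least -0.06, and IFNG at 0.17 in control 4, against at most 0.02.

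Among the EG arrays, EG 1 had the highest mean of IL-13-induced genes, 1.30 against at most 0.57, with CDH26 at 6.11 against at most 3.17 and SOCS1 at 1.24 against at most 0.54. EG 2 had the highest interferon-gamma list mean, 0.97 against at most -0.02. EG 4 had the lowest leukocyte adhesion mean, 0.048 against at least 0.72, and EG 5 the highest intestinal epithelial mean, 0.36 against at most -0.28.

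Lower enteroendocrine genes in EG (list difference -1.40 ± 0.58, SE) were set against 3 technical explanations. The difference was -1.36 ± 0.64 with the 3' to 5' difference as a covariate, and EG 4, with the lowest enteroendocrine mean, also had the lowest 3' to 5' difference of the 10 arrays, -0.30, which argues against RNA quality as the whole cause. Less epithelium in the EG biopsies would lower epithelial junction genes by about as much, and these differed by 0.067 ± 0.12. That list covers epithelium in general, so it cannot decide whether the share of gastric epithelium alone fell. Squamous list means were highest in control 5, EG 1 and EG 5, and without these 3 arrays the enteroendocrine difference was -1.12. Biopsies that reached into the acid-producing part of the stomach would carry more parietal and chief cell genes, which differed by -0.13 ± 0.73, and whether this plays a part cannot be told, because that list varied too much within both groups. Single arrays went both ways. EG 4 had the highest parietal and chief cell mean of the 10 arrays, 1.66, but EG 1 and EG 5, also low in enteroendocrine genes, stood at -1.81 and -0.79. A loss of endocrine cells with the disease may be a further reading, which was not tested, and the list call itself did not hold with an estimated correlation (adjusted p = 0.73).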

How the results depend on the processing

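Added after the data were seen were the exact test of list means, the low-variance filter, the robust prior, the 2 sets of 3 arrays left out and the subepithelial covariate; the others were planned. The cause was not tested for any value below. No paired analysis was possible because the titles in the labels give every sample the same replicate number, and the numbers 1 to 5 used here follow accession order and pair nothing. Not run, because the ratios keep no signal level, were the filters on dim probe sets, the background limited by them and the intensity trend; the largest-variance probe set was already in use. What signal over background limits is unknown for the same reason. List values are adjusted p.

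With repeated quantile normalization 1621 genes stood at an unadjusted p under 0.05, 3 IL-13 and 1 mast cell members passed, leukocyte adhesion (0.00195), plasma cell (0.0395) and smooth muscle (0.00375) lists became called, and the mean turned sign for type I interferon (0.299), neural (0.462) and parietal (0.99) lists. This normalization acted on ratios in which control arrays spread less by construction. It does not show what another normalization of signal levels would give. With arrays centred on their medians 1 mast cell member passed, adhesion (0.0369), smooth muscle (0.0373) and immediate early (0.0465) lists became called, and type I interferon (0.827) and PRG3 (-0.00183) turned sign. With the mean of a gene's probe sets the neutrophil call was lost (0.061), and B cell (0.262) and neural (0.673) lists turned sign. Differences of VWF (0.50 against 0.87), AURKA (0.83 against 1.27) and SIGLEC8 (0.17 against 0.36) shrank. Without probe sets that can match several transcripts the eosinophil (0.0687) and neutrophil (0.163) calls were lost, smooth muscle was called (0.0394), and 1 eosinophil member passed.

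With array weights the unadjusted count was 4775, the fibroblast (0.0719), endothelial (0.0748) and cell cycle (0.116) calls were lost, and type I interferon (0.151), B cell (0.377) and neural (0.431) lists turned sign. With unequal spread 0 IL-13, 0 mast cell and 0 eosinophil members passed, and with exact permutation per gene 0 mast cell and 0 eosinophil members. To pass any member, the exact test needs several members of a list at its smallest possible p, or more at a larger p. With the 3' to 5' difference as a covariate 1 gene was higher, at least 2-fold (GOLIM4, 1.10, adjusted p = 0.0102, chosen after its value was seen), 4 IL-13 and 1 eosinophil members passed, the neutrophil call was lost (0.0663), and B cell (0.429), parietal (0.955) and EPX (-0.00149) values turned sign.

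With an estimated correlation the 10 called lists were each at 0.7345. With fry they stood at 0.1584 (mast cell, IL-13, eicosanoid), 0.2397 (eosinophil, neutrophil, enteroendocrine), 0.3314 (macrophage, cell cycle), 0.3835 (endothelial) and 0.3886 (fibroblast). With the exact test of list means they stood at 0.2 (eosinophil, mast cell, IL-13, enteroendocrine, eicosanoid), 0.222 (neutrophil), 0.3175 (macrophage), 0.506 (fibroblast), 0.431 (endothelial) and 0.2735 (cell cycle). Without genes that another list holds 5 IL-13 and 0 mast cell members passed, the IL-13 (0.115), neutrophil and endothelial (0.0592 each) and eicosanoid (0.0941) calls were lost, and the type 2 list turned sign (0.545). With the low-variance filter adhesion and smooth muscle (0.0402 each) and type 17 and immediate early lists (0.044 each) became called.

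Without the 3 arrays of highest 3' to 5' difference the unadjusted count was 1925, 0 IL-13, 0 mast cell and 0 eosinophil members passed, the macrophage (0.596), fibroblast (0.955) and endothelial (0.881) calls were lost, immediate early genes became called (0.00149), and type I interferon turned sign (0.481). Without the 3 arrays of highest squamous mean the unadjusted count was 1423, 1 IL-13, 0 mast cell and 1 eosinophil members passed, the neutrophil (0.0827), macrophage (0.138), fibroblast (0.555), endothelial (0.172) and cell cycle (0.863) calls were lost, and neural (0.502), parietal (0.737) and ATP4A (0.11) values turned sign. With the subepithelial covariate 0 mast cell and 1 eosinophil members passed, the neutrophil (0.129), macrophage (0.658), fibroblast (0.443), endothelial (0.86), cell cycle (0.0727) and eicosanoid (0.0702) calls were lost, T cell (0.023, lower) and immediate early (0.023) lists became called, and interferon-gamma (0.756), plasma cell (0.658), smooth muscle (0.948) and CCL11 (-0.0322) values turned sign. The covariate is the joint mean of the fibroblast, endothelial and smooth muscle lists, so it takes up their own shifts by construction. The changes of those lists in that setting therefore decide nothing.

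Leaving out each array in turn gave 0 to 111 genes higher, 0 to 130 lower, 0 to 46 at least 2-fold higher and 0 to 72 at least 2-fold lower. The highest of each came without EG 2; the other counts above 0 were 1, MUC4 without control 3 (3.77, adjusted p = 0.0128, chosen after its value was seen) and CDH26 without EG 1 (2.96, 0.0186). The unadjusted count ran from 2166 to 4555. Members passing were 1 to 12 for IL-13, 0 to 8 for mast cell and 1 to 3 for eosinophil lists. The enteroendocrine (2.3e-10 to 2.3e-05), mast cell (2.1e-06 to 0.0234) and IL-13 (0.00276 to 0.0234) calls held in each of the 10. Called lists that lost a call ran from 0.00808 to 0.0778 (eosinophil), 0.00753 to 0.187 (neutrophil), 2.47e-04 to 0.2505 (macrophage), 4.2e-05 to 0.452 (fibroblast), 5.93e-05 to 0.329 (endothelial), 3.06e-05 to 0.14 (cell cycle) and 9.81e-04 to 0.14 (eicosanoid). Lists not called that gained a call or turned sign ran from 0.193 to 0.844 (interferon-gamma), 0.205 to 0.975 (type I interferon), 0.00547 to 0.2505 (adhesion), 0.0273 to 0.335 (type 17), 0.151 to 0.821 (T cell), 0.143 to 0.859 (B cell), 0.00588 to 0.695 (plasma cell), 9.81e-04 to 0.497 (smooth muscle), 0.179 to 0.808 (neural), 0.0167 to 0.171 (gastric surface), 0.0395 to 0.853 (parietal), 0.0238 to 0.821 (intestinal), 0.076 to 0.96 (squamous), 0.289 to 0.89 (junction) and 0.0146 to 0.304 (immediate early). Differences that turned sign ran from -1.14 to 0.31 (ATP4A), -0.0171 to 1.82 (KRT13), -0.0156 to 0.106 (PRG3) and -0.35 to 0.18 (TSLP).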

Other observations

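The tests of explanations and the choice of genes and of the gene family in this part were made after the results were seen; the counts over other splits of the arrays were planned.

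The 5 genes with the smallest unadjusted p belonged to no list. HPDL, a mitochondrial dioxygenase-like gene, was 3.20-fold higher in EG (1.68 ± 0.22, limma adjusted p = 0.172 over all genes), and FNDC3B was 1.96-fold higher (0.97 ± 0.15, adjusted p = 0.172). MPV17L, TRAF5 and MORF4L2-AS1 differed by -0.85 ± 0.13, -0.59 ± 0.09 and -0.55 ± 0.08, with the same adjusted p. For the mean of their probe sets the differences were 0.27 for FNDC3B, -0.41 for MPV17L, -0.24 for TRAF5 and -0.29 for MORF4L2-AS1. In each of the 5 genes the EG and control values did not overlap. Over the alternatives the adjusted p of HPDL ranged from 0.0348 without EG 2 to 0.666.

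Genes named ZNF, most of which encode zinc finger transcription factors, stood lower in EG as a family. Of 502 measured, 365 were lower, 72.7% against 37.9% of other genes, and at an unadjusted p under 0.05 there were 151 lower and 11 higher. Their mean was -0.23 ± 0.08 in EG and 0.002 ± 0.06 in controls, lower on each EG array than on each control array (exact permutation p = 0.00794, the smallest possible). The camera p was 2.9e-17 with the preset and 8.4e-04 with an estimated correlation, for 1 family picked after the ranked genes were seen. The family was lower under each of the 23 alternatives that gave a value, from -0.31 to -0.17.

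For this family, the difference of -0.23 ± 0.05 (SE) was -0.21 ± 0.04 with the 3' to 5' difference as a covariate, -0.21 ± 0.03 after repeated quantile normalization and -0.24 ± 0.05 with the subepithelial list mean as a covariate. The values with covariates argue against RNA quality, as far as ACTB and GAPDH measure it, and the share of subepithelial tissue as the whole cause. The repeated normalization acted on ratios already scaled to the controls. It therefore cannot decide whether the earlier normalization of signal levels plays a part. Whether dim signal plays a part was not tested, since the ratios keep no level. A lower level of these genes in EG tissue may be a hypothesis for other samples.

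The higher mean of mast cell genes in EG (list difference 0.85 ± 0.29, SE; adjusted p = 0.73 with an estimated correlation) was weighed against 2 technical explanations. With the 3' to 5' difference as a covariate the difference was 0.94 ± 0.29, which argues against RNA quality. With the subepithelial list mean as a covariate it was 0.59 ± 0.22, and more subepithelial tissue in the EG biopsies cannot be told apart from more mast cell signal in that tissue, because the value lies within its SE of the bound set for it. A gain of mast cells with the disease stays among the open explanations, untested.

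For genes past the threshold the real split gave 0, which each of the 100 splits reaches by construction, so that count decides nothing about chance, and the highest of the others gave 282. Chance could not be excluded for the other counts. At an unadjusted p under 0.05 the real split gave 3171 genes, 5 of the 100 splits gave as many, and the highest other gave 5492. For the lists, 49 of the 100 splits gave at least the real 10, and the highest other gave 18. Of the other 99 splits 4 gave any gene past the threshold, with 282, 23, 1 and 1, and whether the split with 282 reflects a structure of the samples or chance was not tested.

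Between arrays of 1 group the correlation over genes ran from -0.467 to 0.644 in controls and from 0.154 to 0.71 in EG, where centring on the control median lowers the values of controls by construction. Between the groups it ran from -0.342 to 0.621. EG 2 had 0.621 with control 2 and 0.529 with control 4, above its 0.154 to 0.393 with the other EG arrays. Probe sets with no gene listed were tested apart, and 1 of 11721 passed (243172_at, -1.27 ± 0.13, limma adjusted p = 0.0197), with 1739 at an unadjusted p under 0.05.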
